A study of Apis mellifera with 9 samples.

How the data were processed

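RNA from 9 honey bee larval samples, 3 per diet, was sequenced after library preparation with a TruSeq RNA kit, per the labels' protocols. The authors deposited 1 table of raw read counts per feature, not normalised, with 15314 features named GB and a number with the ending -RA. Its 5 last lines are bookkeeping totals: reads on no feature, ambiguous reads, low-quality, unaligned and non-unique alignments. CASAVA 1.8, HTSeq and edgeR are named in the submitters' processing notes without their roles, and the latter pair without versions. The aligner, genome build, annotation release and strand setting are not given in the sources used here, so no coordinates are reported and overlapping or antisense genes cannot be told apart. The lines for low quality and for non-unique alignment hold 0 reads in every library, which does not show how multi-mapping reads were treated.

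Columns were assigned to diets by their headings. The control and 0.1 mM columns carry replication numbers that match the labels. The 3 columns of 0.25 mM all end in the same number, so each was used as a library of its diet with no number, and no column was left unused. Their counts differ from each other. The labels describe the replications as independent without saying whether they came from separate colonies, so p-values measure the spread between these samples. The bookkeeping lines stayed out of library sizes and tests. On average 13.6%, 13.4% and 12.4% of reads in control, 0.1 mM and 0.25 mM fell on no feature, 3.55%, 3.47% and 3.14% were ambiguous and 17.3%, 17.2% and 17.9% were not aligned.

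Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were kept by filterByExpr with the diet as group, which left 11508 and removed 3806, of which 1348 had no count in any library. Library sizes were scaled by TMM. A quasi-likelihood model (estimateDisp, glmQLFit, glmQLFTest) with 1 coefficient per diet was fitted to all 9 libraries, with 6 residual degrees of freedom, so that the diets share 1 estimate of the spread. Contrasts compared each dose with control and the doses with each other, and a second model fitted dose in mM as a number. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. Fold changes are edgeR's log2 values, their standard errors were taken from the fold change and the F statistic, and 95% intervals used 6 degrees of freedom. CPM values were divided by TMM-scaled library sizes. Intervals do not cover errors shared by all libraries. Comparisons of single values between diets of 3 libraries used an exact two-sided permutation test, whose smallest possible p is 0.1.

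Before the data were examined, the design, the alternatives, a rule for naming genes and 27 gene lists were fixed. The lists covered detoxification enzymes, immunity, nutrition, energy metabolism, growth and markers of other tissues, as patterns over gene names. None could be evaluated, because 0 of 15314 identifiers matched the 12398 genes of the reference table (assembly Amel_HAv3.1), and none of the planned set tests was run. For identifiers without names, the rule gives at most 2 per direction in a comparison: those with the largest change among called genes whose libraries do not overlap between the diets, with a mean of at least 1 CPM. Where no gene was called, those with the smallest p were given as values. Chance alone separates 3 libraries from 3 in 10% of genes.

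The test was tried on simulated counts for these 11508 genes with 200 changed, drawn with the observed means, depths and dispersions. For 0.25 mM against control it recovered 46.3% of genes changed 1.5-fold, 70.1% at 2-fold and 97% at 4-fold, with 11 false calls among 153. For 0.1 mM against control it recovered 47.8%, 85.1% and 97%, with 9 false calls among 162. For 0.25 mM against 0.1 mM it recovered 41.8%, 80.6% and 97%, with 11 false calls among 157, and for the dose trend 52.2%, 77.6% and 95.5% with 11 among 161. Each comparison had a single draw, with genes independent and the same dispersion per gene in all diets. A far larger share of genes, 35.6%, was called in the data at 0.25 mM, so recovery and false calls there can differ from these values. The similarity of the 2 doses was set beside 30 simulations in which no diet differed. The place of 0.1 mM between control and 0.25 mM was set beside another 30, in which 0.25 mM had its observed means and 0.1 mM those of control. Alternatives were other scaling factors (RLE, upper quartile), DESeq2 1.42.0, edgeR's likelihood ratio test, limma-voom (limma 3.58.1), no filter or a filter of at least 5 CPM in 3 libraries, thresholds of 0.1 and 0.01, a test against a 1.2-fold change, only the 6 libraries compared, a replicate block and leaving out each library. Chosen after the data were seen were the removal of the 20 most abundant features, the removal of 0.25 mM libraries b and c together, the test for departure from a line, the simulated ratio of the doses, and the covariance with each library left out.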

Results

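The data are RNA-seq read counts from honey bee (Apis mellifera) larvae reared in the laboratory on a royal jelly diet without quercetin, with 0.1 mM quercetin or with 0.25 mM quercetin. Quercetin is a plant flavonol that bees meet in pollen, nectar and honey, and the comparison asked how larval transcripts differ when it is added to the food. Each diet had 3 libraries, each from a separate replication of 10 to 12 larvae that fed for 3 days. The labels name whole larvae as the source but midguts in the extraction protocol, so the tissue is not settled by them. The table lists 15314 features under GB identifiers, which it does not pair with gene names, and 0 of them matched the reference gene table used here. Changes are therefore described by number, size and abundance of the genes, and no pathway or gene family could be examined.

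Between 34456449 and 42874091 reads per library were counted on features, which was 65.58% ± 0.0243 of all reads in control, 65.87% ± 0.28 at 0.1 mM and 66.57% ± 0.143 at 0.25 mM (SD, n = 3 each). The most abundant feature alone took 8.17% ± 0.117 of the feature counts in control, 8.27% ± 0.32 at 0.1 mM and 9.79% ± 0.494 at 0.25 mM. Both shares were higher in every 0.25 mM library than in every control (exact two-sided permutation test, p = 0.1 each, the smallest that 3 against 3 libraries can give). Replicates of every diet differed by more than counting noise, with a chi-square per degree of freedom between 12.2 and 109.2 for pairs of libraries of 1 diet. All 3 columns of the 0.25 mM diet carry the same heading, and they are called libraries a, b and c here, in table order, as names only. Libraries b and c lay far from the rest on the first principal component of log2 CPM, at 41.7 and 40.8. Library a lay at 1.47, next to the 0.1 mM libraries at -11.3, -6.52 and -0.65, and the controls lay between -25.1 and -19.6.

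**Figure D1:**
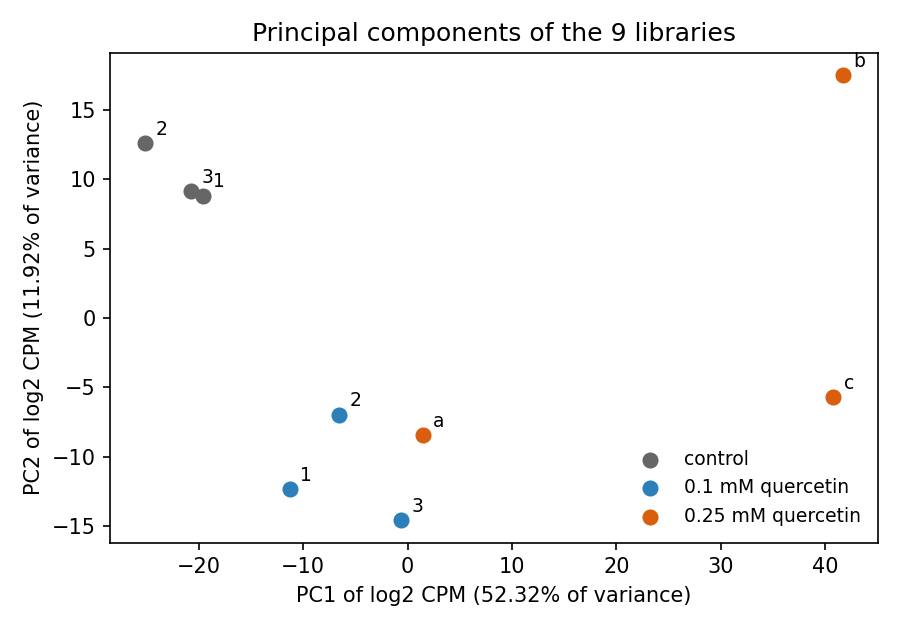
Principal components 1 and 2 of log2 CPM over 11508 genes, with the percentage of variance on each axis. Each point is a library, coloured by diet and marked with its replication number or, at 0.25 mM, its letter. Libraries b and c stand apart on the first component, and library a of the same diet sits beside the 0.1 mM libraries.

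Larvae on 0.25 mM quercetin differed from control in a large part of the transcriptome, mostly by small amounts. Of 11508 genes tested, 1966 rose and 2133 fell, together 35.6% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Which direction held more genes depended on the scaling, the filter, the threshold and the libraries used. Upper-quartile factors gave 2309 higher and 1802 lower, the stricter filter 1872 and 1724, and the removal of the 20 most abundant features, chosen after the data were seen, 2086 and 1983. A threshold of 0.01 gave 398 higher and 324 lower, the 6 libraries compared alone 1224 and 1072, the data without library b 903 and 665, and those without library c 682 and 430. The median change among the 4099 genes called with TMM factors was 1.43-fold. At least 1.5-fold changes were found in 882 genes that rose and 748 that fell, and at least 2-fold changes in 213 and 187. A change of 4-fold or more was seen in 13 genes that rose and 14 that fell.

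The genes that rose accounted for 27.1% ± 0.462 of feature counts in control and 35.6% ± 2.78 at 0.25 mM (SD, n = 3). Those that fell accounted for 17.4% ± 0.279 in control and 11.9% ± 1.76 at 0.25 mM. These shares describe genes picked in the same libraries and are no separate test. The genes with changes of at least 2-fold were minor transcripts as a group. The 213 that rose went from 0.358% ± 0.0177 of counts to 0.819% ± 0.202, and the 187 that fell went from 0.56% ± 0.0097 to 0.201% ± 0.0938. Among the 3836 least abundant genes, with a mean of at most 7.26 CPM, 553 genes rose and 337 fell, and 150 and 113 of them changed at least 2-fold. Among the next 3836 genes, 685 rose and 959 fell. Among the 3836 most abundant genes, with a mean of at least 42 CPM, 728 rose and 837 fell, of which only 24 and 13 reached 2-fold. Among the 20 most abundant features, 6 rose, 1 fell and 13 did not pass the test. The single most abundant feature was higher by 0.34 ± 0.106 on the log2 scale (± SE; edgeR, adjusted p = 0.0353), from a control level of 80240 CPM.

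The 2 largest increases among called genes were highest in library c. GB52184-RA averaged 0.249 ± 0.148 CPM in control and 5.25 ± 7.29 CPM at 0.25 mM (SD, n = 3), a log2 fold change of 4.34 ± 1.13 (± SE; edgeR, adjusted p = 0.0199). Its value was 13.7 CPM in library c, against 0.951 in a and 1.12 in b, and the log2 fold change without library c was 2.03. Its call was lost without control 1, 2 or 3 (edgeR, adjusted p = 0.0553, 0.0732 and 0.0572), in limma-voom and against a 1.2-fold change, with an adjusted p of at most 0.115 over the alternatives that gave one. DESeq2 gave it no adjusted p, and the stricter filter left it out. GB49890-RA rose from 6.94 ± 2.46 to 119 ± 124 CPM, by 4.09 ± 0.907 on the log2 scale (edgeR, adjusted p = 0.0128). It reached 261 CPM in library c, 61 in b and 34.3 in a, and its log2 fold change was 2.79 without library c. Of the 9 libraries, only the omission of control 2 ended its call (edgeR, adjusted p = 0.0527). The 2 largest decreases were in genes whose controls varied widely. GB46518-RA fell by 3.98 ± 1.11 on the log2 scale (edgeR, adjusted p = 0.0244), from control values of 0.909, 12.8 and 7.08 CPM to 0.434 ± 0.348 CPM. GB47116-RA fell by 3.93 ± 1.18 (edgeR, adjusted p = 0.0307), from 43.2, 163 and 147 CPM to 7.72 ± 4.89 CPM. Neither decrease passed the test when control 2, control 3, library b or library c was left out, with adjusted p between 0.0541 and 0.11 in edgeR. Neither passed a test against a 1.2-fold change, GB46518-RA did not pass in limma-voom, and the adjusted p was at most 0.285 over the alternatives run, of which the stricter filter left out GB46518-RA.

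The number of genes called at 0.25 mM depended on single libraries. It was 6491 without library a, 1568 without b and 1112 without c, and 2698, 1405 and 1908 without control 1, 2 and 3. With libraries b and c both left out, 7 of the 4099 genes had a fitted change of the opposite sign in library a alone against control. Library a and the same controls had helped to choose these 4099 genes, so the shared direction is partly built in and is no separate test. The spread of the lone library was assumed equal to that of the other diets, and this omission was chosen after the data were seen.

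At 0.1 mM quercetin, 8 genes rose and none fell relative to control (edgeR quasi-likelihood test, adjusted p = 0.0436 for each). Their log2 fold changes ran from 0.46 to 1.63, and all 8 were also called as higher at 0.25 mM. Of the 8, 3 had the larger change at the higher dose. They were picked by their call at 0.1 mM, which favours large changes there, so this says nothing about the shape of the response. An unadjusted p under 0.05 was found for 1037 genes, or 9.01%, and DESeq2 called 147 genes, of which 118 were higher. For 10230 of the 11500 genes that were not called, the 95% interval of the difference excluded a 2-fold change in either direction. For the other genes a 2-fold change was not excluded with these libraries. The count of 8 became 112 without library a. Without library c 2 of the 8 were called, without 0.1 mM replicate 1 a pair of genes of which 0 were among the 8, and without any other single library 0. It was 113 in edgeR's likelihood ratio test and 0 in limma-voom, with the replicate number as a block and with the stricter filter. With only the 6 libraries of the 2 diets it was 38, of which 32 were higher and 6 lower. In that fit, 2049 genes had an unadjusted p under 0.05.

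Among the 8 genes called at 0.1 mM, the 2 largest increases were in features with consecutive identifiers. GB41221-RA rose from 0.945 ± 0.28 CPM in control to 2.93 ± 0.382 at 0.1 mM (SD, n = 3), a 3.1-fold change with a log2 value of 1.63 ± 0.221 (± SE). GB41222-RA rose from 13.2 ± 1.72 to 37.6 ± 6.9 CPM, 2.84-fold, with a log2 value of 1.51 ± 0.191. At 0.25 mM they stood at 3.43 ± 0.427 and 51.5 ± 11.8 CPM, with log2 fold changes against control of 1.86 and 1.96 (edgeR, adjusted p = 0.00389 and 0.00348). In both genes the 3 libraries of 0.25 mM, library a included, lay above all 3 controls, as the naming rule requires only of the 0.1 mM libraries. At 0.1 mM these calls were close to the threshold, and each was lost when any control or any 0.1 mM library was left out, with adjusted p between 0.082 and 0.246 in edgeR. Both calls were also lost without library b, in limma-voom, with the replicate block and against a 1.2-fold change, and that of GB41221-RA without library c. Whether the counting could split reads between neighbouring copies is not given in the sources used here.

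**Figure D2:**
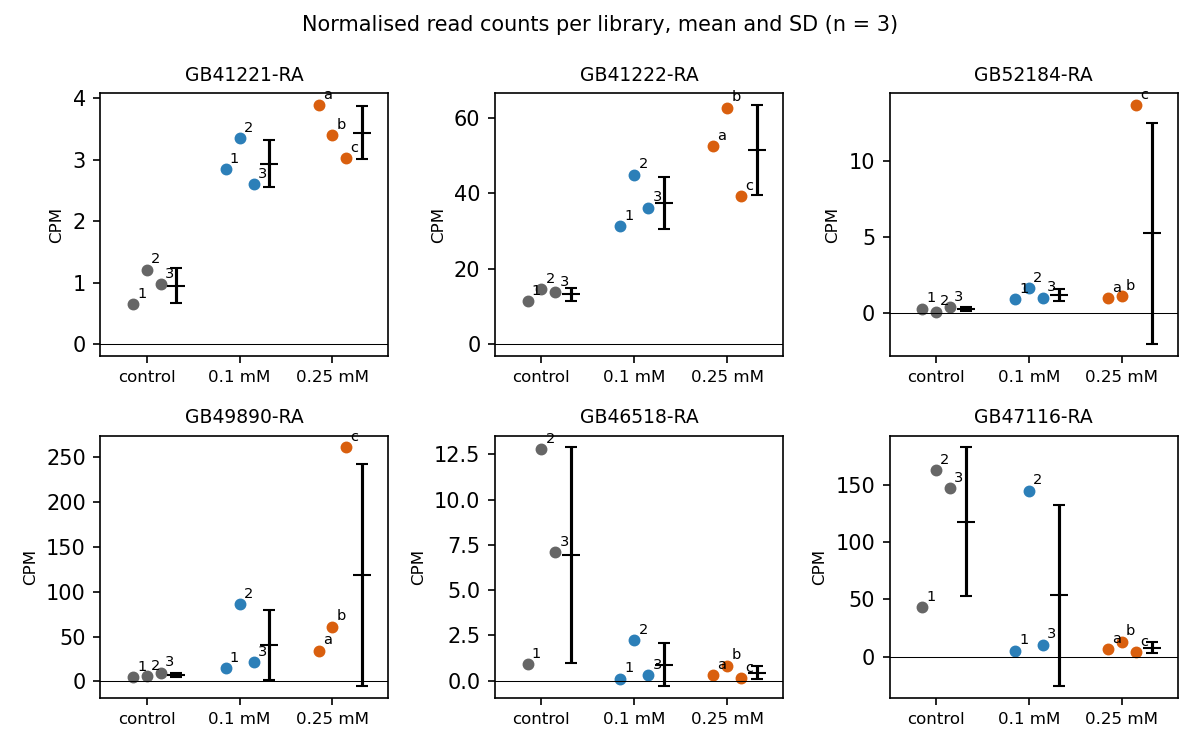
Normalised read counts (CPM, vertical axes) of the 6 features named for the comparisons against control, by diet. Points are libraries marked with number or letter, and the black bars give the mean ± SD (n = 3). Features were named only if the libraries of the compared diets did not overlap, and GB52184-RA and GB49890-RA peaked in library c.

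No gene passed the test between 0.25 mM and 0.1 mM quercetin in edgeR's quasi-likelihood fit, where the smallest adjusted p was 0.0774. Without library a, 5367 genes were called, 2485 higher and 2882 lower at 0.25 mM. An unadjusted p under 0.05 was found for 3925 genes, or 34.1%. DESeq2 called 2111 genes, edgeR's likelihood ratio test 1524 and limma-voom 0. The genes with the smallest p were GB47506-RA and GB52185-RA, with log2 differences of 0.88 (95% interval 0.607 to 1.16) and 0.77 (0.504 to 1.03), and GB50678-RA and GB42458-RA, with -0.66 (-0.884 to -0.434) and -0.53 (-0.726 to -0.34). GB47506-RA averaged 32.7 ± 2.22 CPM in control, 43 ± 3.44 at 0.1 mM and 79.3 ± 12.3 at 0.25 mM, and GB50678-RA 46.1 ± 4.84, 34.4 ± 1.75 and 21.8 ± 1.37 CPM (SD, n = 3 each). For 9519 of the 11508 genes, the 95% interval excluded a 2-fold difference between the doses.

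Across the 3 doses, 4417 genes had a linear trend, 2113 upward and 2304 downward (edgeR quasi-likelihood test of the slope, adjusted p under 0.05). With upper-quartile factors, 2477 were upward and 1970 downward, with the stricter filter 1993 and 1851, and without the 20 most abundant features 2237 and 2167. Without library b they were 1153 and 956, without library c 935 and 713, and at a threshold of 0.01 720 and 656. The fitted change over 0.25 mM was at least 2-fold in 220 rising and 202 falling genes. Without library c 1648 genes had a trend, without library b 2109 and without library a 5982. No gene departed from a straight line in dose after adjustment in edgeR (465 of 11508 at an unadjusted p under 0.05), a test chosen after the data were seen. It was run only with library a included and its power was not measured, so it does not show that the response was linear. Of the 4099 genes called at 0.25 mM, 3821, or 93.2%, had their 0.1 mM mean between control and 0.25 mM. In simulations with 0.25 mM changed as observed and 0.1 mM unchanged, 60.7% of called genes did so, with 62.5% as the highest of 30 simulations. The median ratio of the log2 change at 0.1 mM to that at 0.25 mM was 0.342 for genes that rose and 0.275 for genes that fell, beside a dose ratio of 0.4. In the same 30 simulations, where only the shared controls and the choice of genes act, it averaged 0.0716 (0.052 to 0.0838) and 0.0704 (0.0611 to 0.0818). The simulations drew each gene independently. A shift common to many genes in a library is therefore not covered, and neither the simulated percentages nor these ranges measure it.

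Both doses were compared with the same controls, which makes their fold changes alike by chance. Across genes, which are not independent replicates, the log2 fold changes at the 2 doses correlated with r = 0.671, against a mean of 0.502 in 30 simulations with no diet effect. The covariance was 0.0819 observed and 0.0241 ± 0.00138 simulated (SD), a difference of 0.0578. This SD comes from genes drawn independently and does not measure the spread between sets of libraries. With 1 library left out, an omission chosen after the data were seen, the observed covariance ran from 0.0714 to 0.101. No simulation was run for these omissions, and fewer shared controls raise the covariance by themselves. The range can therefore not be set beside the simulated 0.0241. The sign was shared by 76.4% of genes, against 66.8% in the simulations. Of the calls, 8 higher genes were shared, where independent lists of these sizes would share 1.37, a value that leaves out the shared controls. In the simulations with no diet effect, which share the controls, the highest overlap of calls was 0. Few calls are expected at either dose without an effect, so this 0 is largely built in. It does not show how many calls the shared controls alone would make common when the higher dose has many. The simulations with no diet effect drew each gene independently. A deviation common to many genes in the shared controls may still be part of the excess, since 3 libraries cannot be split into groups of at least 2.

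**Figure D3:**
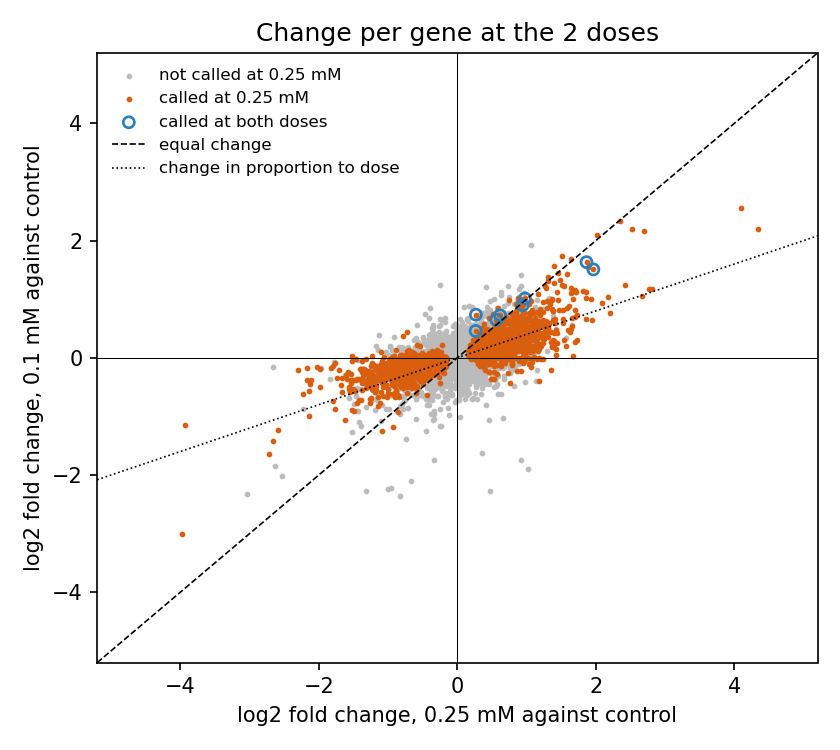
Log2 fold change of each of 11508 genes at 0.1 mM (vertical) and 0.25 mM (horizontal) against control. Orange points are the 4099 genes called at 0.25 mM, blue rings the 8 called at both doses, the dashed line marks equal change and the dotted line a change in proportion to dose. Most orange points lie between the horizontal axis and the dashed line.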

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

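The 3 tests of library a in this part were chosen after its position had been seen. Unaligned reads lie outside the comparisons of the report, and their share at 0.25 mM, 17.9% ± 0.526, exceeded the highest control library at 17.7%, beside a control mean of 17.3% ± 0.37, a difference within the spread between libraries (exact two-sided permutation test, p = 0.2, n = 3 each, where 0.1 is the smallest possible). The excess was in libraries b and c, at 18% and 18.4%, while library a had 17.3%.

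In its gene values as a whole, library a of the 0.25 mM diet lay near the 0.1 mM libraries: on an axis from the control mean at 0 to the mean of b and c at 1, it lay at 0.384 and they at 0.205, 0.268 and 0.355. Not every measure placed it there, since its chi-square per degree of freedom was 20 and 37.5 with 0.1 mM replicates 1 and 2 but 83.8 with replicate 3, against 109.2 with b and 77.3 with c. A swap with a 0.1 mM library is argued against, as the highest library labelled 0.1 mM lay at 0.355, while the part of a few abundant features stays undecided, because leaving out the 20 most abundant moved no library by more than 0.00125 (library a to 0.385). Also open are a single wrong label, as 0.384 lies within 1 SD (0.0756) of the 0.1 mM range, and a weaker response in 1 replication, which was not tested. Some shares of library a, which were not tested, lay beyond the 0.1 mM range on the side of b and c: 66.5% of reads assigned (at most 66.2% at 0.1 mM), 12.9% on no feature (at least 13.2%), 3.36% ambiguous (at least 3.44%), 9.26% of counts in the most abundant feature (at most 8.56%) and 23.6% in the top 20 (at most 22.3%). These shares depend on each other, and a further library of the same diet can easily exceed a range of 3, so they do not decide on the label.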

How the results depend on the processing

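The removal of libraries b and c together, of the 20 most abundant features, and of single libraries for the covariance were chosen after the data were seen. The count at 0.1 mM was 8 in the fit of the report. It was 13 with upper-quartile factors, 147 with DESeq2, 113 with the likelihood ratio test, 0 with limma-voom, 15 without a filter, 0 with the stricter filter, 28 and 0 at thresholds of 0.1 and 0.01, 38 with only the 6 libraries of the comparison, 0 against a 1.2-fold change, and 0 to 112 with 1 library left out. At 0.25 mM, 4099 genes became 722 at a threshold of 0.01, 2296 with only 6 libraries, 693 against a 1.2-fold change, 82 without libraries b and c, and 1112 to 6491 with 1 library left out; other scalings, tests and filters gave 3596 to 4553, and the removal of the 20 most abundant features 4069. Between the doses, 0 became 2111 with DESeq2, 1524 with the likelihood ratio test, 2426 at a threshold of 0.1, and 0 to 5367 with 1 library left out. The trend, 4417 genes, fell to 1376 at a threshold of 0.01 and ranged from 1648 to 5982 with 1 library left out. The covariance of the doses, 0.0819, was 0.0583 with the stricter filter and 0.0714 to 0.101 with 1 library left out. Library a belongs to neither diet of the 0.1 mM comparison. Its removal, which took the count there from 8 to 112, could thus act only through the shared filter, scaling or spread. Without library a, 11596 genes were tested instead of 11508, and the median log2 change was 0.00188 instead of -0.00457. The genes with an unadjusted p under 0.05 in edgeR rose from 1037 to 2200. Upper-quartile factors moved that median further, to 0.0129, and no filter left 13966 genes, yet they gave 1055 and 1057 such genes. This argues against the filter and the scaling as the main source. The spread was not tested on its own, nor was why other tests or single libraries moved a count. None of the 10 named features changed direction in any alternative that gave it a value. They were named for separated libraries or for the smallest p, so a stable direction is largely built in and is no separate test. With the replicate block, possible only for control and 0.1 mM because the 0.25 mM columns carry no number, 0 genes were called at 0.1 mM. Deviations of libraries were taken as log2 CPM minus the mean of their diet. In these, same-numbered libraries of the 2 diets did not deviate together (r = -0.0818, 0.0994 and -0.123). Of the 0.1 mM libraries, replicate 3 had the highest correlation of deviations with control 1 (0.233). The planned gene set alternatives, the block for comparisons with 0.25 mM and for the agreement of doses were not run.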

Other observations

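No test in this part was chosen after its result was seen. Genes with consecutive identifier numbers tended to change in the same direction at 0.25 mM. Of 9184 pairs of tested neighbours, 400 were both higher and 505 both lower, 905 in all, against a mean of 611 and a highest of 671 in 1000 permutations of the calls within 10 classes of abundance (permutation p = 0.001, one-sided, the smallest these permutations can give). Pairs called in opposite directions were fewer, 412 against a mean of 605.4. Similar abundance of neighbours is thus argued against as the whole cause. The pattern may not be specific to the diet: among abundant genes the neighbour correlation of the 0.25 mM change was 0.151, and contrasts within the control libraries gave 0.0818 to 0.235, the highest being 1.55 times the value of the diet. This is what covariance of neighbours in any libraries would give, for example from overlapping features or reads shared between adjacent copies, or from neighbours that are regulated together in every diet, and these were not separated. The files do not say how numbers relate to positions in the genome.

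Other groupings of the same libraries were tested as well. For 0.1 mM against control, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 8 genes, and the highest other split gave 0. For 0.25 mM against control, 1 of 10 splits reached 4099 genes and the highest other gave 0. For 0.25 mM against 0.1 mM the real split gave 0, so all 10 reached it, and the highest other gave 5. With 10 splits no share under 0.05 can arise. For the dose trend, 1 of 100 assignments of the doses to the 9 libraries, the real one, reached 4417 genes, and the highest other gave 1821. This argues against a chance assignment as the source of a count this large, but 100 assignments cannot exclude it. Nor can they tell the diet from another difference between the same libraries.

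The 2 features named for the largest decreases also differed between replicates of 1 diet. GB47116-RA stood at 145 CPM in 0.1 mM replicate 2 but at 5.22 and 10.3 CPM in replicates 1 and 3, and GB46518-RA at 2.23 against 0.107 and 0.299 CPM. In both features control 1 was the lowest control, at 43.2 and 0.909 CPM.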
